A study of Mus musculus with 4 samples.

How the data were processed

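RNA was sequenced from lineage-depleted bone marrow cells of 2 wild type and 2 Cyba knockout mice, per the series' design text. Per the labels' protocols, marrow was flushed from leg and hip bones, red cells were lysed, lineage-negative cells were isolated with a magnetic depletion kit, and libraries were made from 2 micrograms of total RNA with the Illumina TruSeq RNA kit v2. The submitters' processing notes name Salmon, DESeq2 and the genome build GRCm38; versions, the transcript annotation and the strand setting were not given in the sources used here. Each library was deposited as 1 table of estimated counts (expected counts per gene) and 1 table of TPM values by the authors, each with 22520 Ensembl genes and 4 columns that are sequencing lanes per the file headers. The lanes are runs of 1 library and were summed.

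The deposited tables of estimated counts and TPM had lost decimal points: a number with at least 3 decimals and a whole part above 0 stood as an integer of up to 6 digits, whereas whole numbers, numbers under 1 and numbers with at most 2 decimals were intact. In wild type replicate 1, for example, Cyba stood at 303, 343, 375067 and 326 in the 4 lanes. Of 360320 count values, 24.8% had more than 1 possible reading, and of the TPM values 53.1%; none of the 75261 count values of 6 digits ended in 0. As deposited, the lanes summed to between 1700352247 and 1839185684 counts. The readings were therefore weighed jointly for each gene. The model let the lanes of a library share 1 rate (negative binomial), tied each TPM value to its count through the gene's length, and let the libraries differ through a heavy-tailed distribution (t with 3 degrees of freedom, scale 0.2 on the natural log scale). A gene was kept if the expected error of each library total was at most 5% or 1 read. This kept 22054 genes, 10830 of them with no damaged count, and left out 466. The repaired lanes summed to between 1005247 and 1023844 TPM, where TPM sums to 1000000 by definition. Repairing with no tie between the levels of the libraries kept 20059 genes. For all 20020 genes kept both ways the library totals agreed within 5% or 1 read. Gene length and the pattern of decimals were still fitted over all 4 libraries, so this agreement is partly built in. The values below are thus the authors' estimated counts after this repair, and a small share of them may be read wrongly. In a simulation of the comparison over the 22054 kept genes, damaged and repaired in the same way, 98.6% were kept. Of these, 8 had a library total off by over 5% and 1 read. Simulated changed genes, drawn from well expressed genes, were lost more often: 187 of 200 were kept, and 44 of the 50 with 10-fold changes. Of the 466 real genes left out, 280 had a mean of at least 40 reads per library, so some genes that differ between genotypes may be missing.

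Gene names and coordinates came from GENCODE vM21 (GRCm38), which matched 22384 of the identifiers without their version; 136 did not match. Library sums were rounded to whole numbers. The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM factors and the default expression filter by genotype, which left 13784 genes, with Benjamini-Hochberg adjustment, an adjusted p threshold of 0.05 and two-sided p-values. The SE of a log2 fold change is its size divided by the root of the F statistic. CPM values use TMM-scaled library sizes, and SD is over 2 libraries. Groups came from the sample titles, each library being 1 mouse.

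Gene lists were fixed before the data were examined: 31 lists with 649 different genes, of which 30 lists had at least 5 tested members and were tested with camera of limma 3.58.1 (preset correlation 0.01, prior count 2 for log2 CPM), adjusted over the lists. The list of sex-linked genes was left out of the tests. They cover the NADPH oxidase, the neighbours of Cyba, stem and progenitor cells, the cell types that a depletion can leave, cell division, stress and metabolism. Named genes were also set by rule. The rule took up to 12 genes per direction among those passing, and where fewer than 5 passed, the 10 of that direction with the smallest p. Both knockout libraries had to lie on the same side of both wild type libraries, with a mean log2 CPM of at least 1 and a symbol that was not a predicted model. Cyba and up to 3 members of each list with the smallest p were added. Some of the genes this rule took are not reported here. Alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, limma-trend on log2 TPM with a pseudocount of 1 or 0.1 for 11150 genes with settled TPM values), other thresholds, the replicate number as a block and leaving out each library. Python 3.11.15 and numpy 2.4.6 were used for the repair.

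The tests were tested on simulated data with the means and library sizes of these libraries, a biological coefficient of variation of 0.24 and 200 changed genes. Of the changed genes that were tested in this simulation of knockout against wild type (13630 genes), edgeR called 0 of 49 with 1.5-fold, 6 of 50 with 2-fold, 44 of 44 with 4-fold and 43 of 44 with 10-fold changes, and made 8 false calls. DESeq2 called 1 of 49, 6 of 50, 44 of 44 and 43 of 44, with 14 false calls among 12367 genes. The simulation gave every gene the same spread, drawn independently, so its detection rates do not carry over to the real data. In the real data the spread of single genes was estimated with 2.46 prior degrees of freedom. There edgeR gave Cyba an adjusted p of 0.305 at a log2 fold change of -5.19, so 0 calls do not exclude large changes.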

Results

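The data set held RNA-seq profiles of bone marrow cells from C57BL/6 mice after magnetic removal of cells carrying markers of mature blood lineages, a fraction enriched for haematopoietic stem and progenitor cells. The genotypes were wild type, with 2 mice, and a knockout of Cyba, with 2 mice. Cyba encodes p22phox, the membrane subunit that NADPH oxidases need to make superoxide. The series title names the questions behind the comparison, which are the number of stem cells, a shift towards myeloid cells and a loss of B-cell differentiation in the knockout. The summed estimated counts were 23709890 and 22426815 reads for wild type replicates 1 and 2, and 23127631 and 22891335 for Cyba knockout replicates 1 and 2, so depth differed little between the groups. Mitochondrially encoded genes took 3.26% and 3.53% of the reads in the wild type libraries and 3.07% and 2.84% in the knockout libraries. Immunoglobulin genes took 2.94% and 0.572% in wild type replicates 1 and 2, and 4.15% and 1.66% in knockout replicates 1 and 2. The Y-linked gene Kdm5d had 77, 57, 69 and 70 reads in wild type 1 and 2 and knockout 1 and 2, in that order. Of the other Y-linked genes, in the same order, Uty had 17, 16, 12 and 18 reads, Ddx3y 3, 3, 2 and 6, and Eif2s3y 0, 5, 1 and 1, so all 4 genes were low or nearly absent in every library.

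Cyba transcripts were nearly lost from both knockout libraries. Cyba (ENSMUSG00000006519, protein-coding, GRCm38 chromosome 8, 122424776 to 122432930, minus strand, 7 merged exons with no base shared with another annotated gene) had 1347 and 875 reads in wild type replicates 1 and 2 and 28 and 32 reads in knockout replicates 1 and 2. Its level was 47.8 ± 12.5 scaled counts (CPM, mean ± SD, n = 2) in wild type and 1.31 ± 0.0861 CPM (SD, n = 2) in the knockout, a log2 fold change of -5.19 (SE 0.28). Every library therefore matched its label. In the edgeR quasi-likelihood test Cyba had the smallest p of all genes, and after Benjamini-Hochberg adjustment over 13784 genes its edgeR adjusted p was 0.305. With DESeq2 the adjusted p of Cyba was 2.7e-44 at a log2 fold change of -5.20. Cybb, the catalytic partner of p22phox in phagocytes, stood at 81.0 ± 7.83 CPM in wild type and 189 ± 42.0 CPM in the knockout (log2 fold change 1.23, SE 0.20, edgeR adjusted p = 0.841, DESeq2 adjusted p = 0.00335). Of the 12 measured members of the NADPH oxidase list, 0 passed over all genes and 2 passed when adjusted over the list alone, Cyba (adjusted p = 0.00027) and Cybb (adjusted p = 0.0149). Nox4, another catalytic subunit, was at 0.976 ± 0.0697 CPM in wild type and 0.391 ± 0.112 CPM in the knockout without passing. As a set the list was not called (camera adjusted p = 0.0955), and its median log2 fold change of 0.44 and its mean of -0.12 differed in sign, and Cyba itself had by far the largest difference. The list was called higher without wild type replicate 1 (camera adjusted p = 0.0307). The 14 measured genes that neighbour Cyba on chromosome 8 were split evenly, 7 higher and 7 lower, and were not called (median log2 fold change 0.03, camera adjusted p = 0.477). Their member with the smallest p, Mvd, stood at 7.86 ± 1.98 CPM in wild type and 16.1 ± 2.43 CPM in the knockout.

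**Figure D1:**
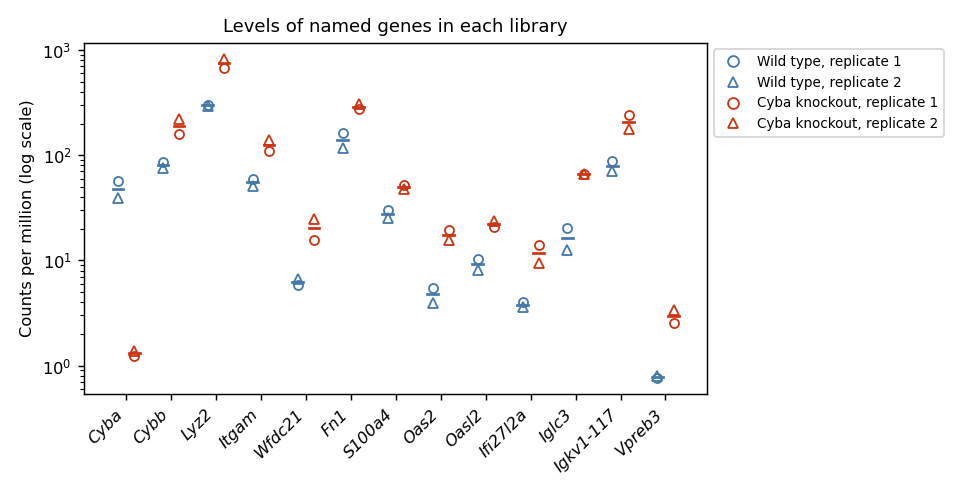
Levels of 13 named genes in CPM on a log axis; open circles are replicate 1, open triangles replicate 2, blue is wild type, red is the Cyba knockout, and short lines are the means of 2 libraries. Cyba fell from 47.8 to 1.31 CPM on average (DESeq2 adjusted p = 2.7e-44). The other genes were picked from the named genes with both knockout libraries above both wild type libraries, so this separation is not a result. Named genes that overlapped or, other than Cyba, were lower are not drawn.

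Over all genes, more of those with a small p were higher than lower in the knockout. With the edgeR quasi-likelihood test 0 genes passed in either direction at an adjusted p of 0.05. Of 13784 genes 448 had an unadjusted p under 0.05, a smaller share than the 0.05 expected if no gene differed. Of these 448, 383 were higher and 65 lower in the knockout. Both knockout libraries lay above both wild type libraries for 2426 genes and below both for 2226. Together these were 33.75% of the tested genes, against 33.33% by chance if every split of the 4 libraries were equally likely. Deviations of same-numbered libraries correlated at 0.613 across genes, so the splits were not equally likely. The comparison with 33.33% therefore neither shows nor excludes an excess. All genes other than Cyba had an adjusted p of at least 0.841. DESeq2, the tool named in the submitters' processing notes, called 31 genes, 29 higher and 2 lower. The edgeR likelihood ratio test called 28 and limma-voom 0. The 10 genes higher in the knockout that the naming rule took, none of which passed with the edgeR quasi-likelihood test, were Lyz2, Iglc3, Oas2, AB124611, Itgam, Slco4c1, Pirb, Oasl2, Apobr and a kappa variable segment of the Igkv1 family. All 10 passed with DESeq2. Lyz2, lysozyme of monocytes, macrophages and granulocytes, stood at 299 ± 4.80 CPM in wild type and 749.6 ± 111 CPM in the knockout (SD, n = 2), a log2 fold change of 1.33 (SE 0.16, DESeq2 adjusted p = 3.6e-06). Itgam, the integrin CD11b of myeloid cells, stood at 55.6 ± 5.82 and 125 ± 21.5 CPM in the same order (DESeq2 adjusted p = 0.00289). Pirb, an inhibitory receptor of myeloid and B cells, stood at 27.1 ± 2.10 and 57.9 ± 9.35 CPM. Among the immunoglobulin segments, Iglc3 rose with DESeq2 from 16.3 ± 5.41 to 66.3 ± 0.0384 CPM (log2 fold change 2.01, adjusted p = 4.5e-07), and the Igkv1 segment stood at 79.5 ± 12.3 and 209 ± 46.3 CPM. Slco4c1, an organic anion transporter, had a log2 fold change of 1.98 (SE 0.30), and Apobr, a lipoprotein receptor, one of 1.00 (SE 0.16).

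On the lower side the naming rule took Cyba and 9 genes with smaller differences, and of these 10 only Cyba passed with DESeq2. Ighv1-55 stood at 187 ± 59.96 CPM in wild type and 83.3 ± 16.0 CPM in the knockout, and Ighv1-47 at 3.71 ± 0.547 and 1.17 ± 0.521 CPM. Odc1, the rate-limiting enzyme of polyamine synthesis, stood at 403 ± 17.3 and 305 ± 10.8 CPM (log2 fold change -0.40, SE 0.12, edgeR adjusted p = 0.841). The aminoacyl-tRNA synthetases Iars and Cars had log2 fold changes of -0.38 (SE 0.12) and -0.42 (SE 0.14). Dyrk3, Nutf2, Rab27b and Atxn2 lay between -0.61 and -0.35. The other gene that DESeq2 called lower was Fam177a (log2 fold change -3.53, adjusted p = 0.0495), whose reads were 48 and 516 in wild type replicates 1 and 2 and 25 in each knockout library, so that wild type replicate 2 set most of the difference. Immunoglobulin segments, Lyz2, the Oas genes and Pirb have close copies in the genome, and Itgam and S100a4 share 68.7% and 51.7% of their exonic bases with an overlapping annotated gene, so their counts depend on how reads were divided.

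Interferon-induced genes were higher in both knockout libraries. The list of genes induced by type I interferon rose as a set, with 27 of 28 measured members higher, a median log2 fold change of 0.69 and a camera adjusted p of 2.4e-15 at the preset correlation. The call was lost at a camera adjusted p = 0.334 with an estimated correlation, which was -0.023 for this list. In that setting camera has only the 2 residual degrees of freedom of 4 libraries. Both knockout libraries lay above both wild type libraries for 24 of the 28 genes. For a single gene the chance share is 16.7% if every split of the libraries is equally likely. All members share an inducer and were measured in the same 4 mice, so these 24 genes do not count as separate comparisons of genotype. The list's median deviation from the mean of the 4 libraries was -0.36 and -0.35 in wild type replicates 1 and 2 and 0.40 and 0.29 in knockout replicates 1 and 2. Over all genes 0 members passed with the edgeR quasi-likelihood test, and adjusted over the list alone 3 passed, namely Oas2, Oasl2 and Ifi27l2a. Oas2, a sensor of double-stranded RNA, stood at 4.74 ± 1.10 CPM in wild type and 17.5 ± 2.84 CPM in the knockout (log2 fold change 1.88, SE 0.27, edgeR adjusted p = 0.0297 when adjusted over the list alone). Oasl2 stood at 9.21 ± 1.498 and 22.3 ± 1.99 CPM, and Ifi27l2a at 3.803 ± 0.337 and 11.8 ± 3.29 CPM. All 3 passed with DESeq2 over all genes, with adjusted p = 7.1e-05, 0.00666 and 0.00975.

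Genes of neutrophils and monocytes were also higher on average in the knockout libraries. The maturing neutrophil list rose, with 26 of 26 measured members higher, a median log2 fold change of 1.66 and a camera adjusted p of 5.3e-11 (adjusted p = 0.797 with an estimated correlation). Its median deviation was -1.31 and -0.09 in wild type replicates 1 and 2 and -0.11 and 1.61 in knockout replicates 1 and 2. The medians of wild type replicate 2 and knockout replicate 1 were thus alike. Both knockout libraries lay above both wild type libraries for 13 of the 26 members. Among the others, Ly6g, Ltf and Mmp9 had deviations of 0.59, 0.54 and 0.49 in wild type replicate 2. In knockout replicate 1 these were -1.35, -1.12 and -1.08. Adjusted over the list alone 5 members passed with the edgeR quasi-likelihood test, and 0 passed over all genes. These were Itgam, Wfdc21 (6.29 ± 0.558 CPM in wild type and 20.2 ± 6.33 in the knockout), Mcemp1 (9.66 ± 0.0810 and 24.5 ± 7.499 CPM), and, outside the naming rule and chosen after their values were seen, Chil3 and Padi4 with log2 fold changes of 1.92 and 0.87. The monocyte list rose as well, with 19 of 20 members higher, a median of 0.68 and a camera adjusted p of 9.7e-10 (adjusted p = 0.797 with an estimated correlation). Adjusted over the list alone 2 of its members passed, Fn1, fibronectin (140 ± 30.5 CPM in wild type and 290 ± 24.8 in the knockout), and S100a4 (27.8 ± 3.35 and 49.4 ± 3.13 CPM). Over all genes 0 passed with the edgeR quasi-likelihood test. The granulocyte-monocyte progenitor list was called higher as a set, with 22 of 22 members above 0 and a median of 0.67 (camera adjusted p = 2.5e-07, adjusted p = 0.797 with an estimated correlation). Of its members 0 passed either adjustment, and both knockout libraries lay above both wild type libraries for 9 of 22. The chance share for a single gene is 16.7%, but the estimated correlation between members was 0.97. The 22 members therefore do not count as separate measurements, and 9 of 22 shows no excess. Among them Ly6c2 stood at 543 ± 205 CPM in wild type and 990.2 ± 248 CPM in the knockout, and Csf3r, the G-CSF receptor, at 107 ± 40.9 and 181 ± 20.1 CPM. Wild type replicate 2 was the lowest library for this list, at -0.80 against 0.10 in wild type replicate 1, 0.61 in knockout replicate 1 and 0.05 in knockout replicate 2.

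Calls of other myeloid lists changed when single libraries were left out. The plasmacytoid dendritic cell list rose with 13 of 14 members higher (median 0.44, camera adjusted p = 0.00012), and 1 member, Klk1, passed when adjusted over the list alone, at 1 and 0 reads in wild type against 17 and 22 in the knockout. The conventional dendritic cell list rose with 14 of 15 higher (median 0.53, camera adjusted p = 0.00776), and the eosinophil list with 9 of 9 higher (median 1.20, camera adjusted p = 0.0215). With an estimated correlation the adjusted p was 0.797 for each of these 3 lists. Without wild type replicate 2 the adjusted p was 0.0788 for plasmacytoid dendritic cells, 0.461 for conventional dendritic cells and 0.259 for eosinophils. Without knockout replicate 1 it was 0.383 for conventional dendritic cells, and the eosinophil list then lay lower in the knockout (adjusted p = 0.618). The eosinophil granule gene Prg2 stood at 434 and 254 CPM in wild type and at 1366 and 392 CPM in knockout replicates 1 and 2. Macrophage genes were not called (11 of 16 higher, median 0.17, camera adjusted p = 0.529), and neither were basophil and mast cell genes (12 of 13 higher, median 0.44, camera adjusted p = 0.0693), although the latter were called higher without wild type replicate 1 (adjusted p = 0.000549) or knockout replicate 2 (adjusted p = 0.000194). The macrophage list was called in opposite directions by leaving out single libraries, lower without wild type replicate 1 (adjusted p = 0.0425) or knockout replicate 1 (adjusted p = 0.00941) and higher without wild type replicate 2 (adjusted p = 5.4e-05) or knockout replicate 2 (adjusted p = 0.000886).

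**Figure D2:**
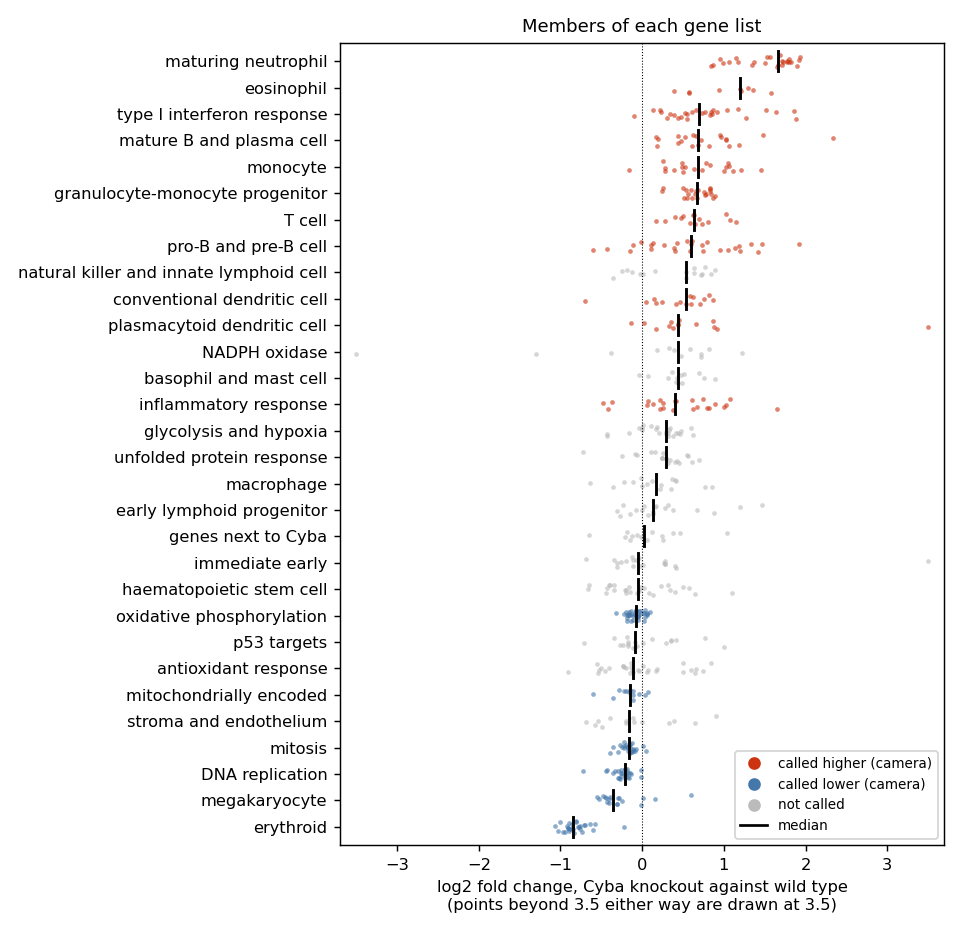
Log2 fold changes of the Cyba knockout against wild type for the measured members of 30 gene lists fixed before the data were examined, one point per gene, with the median as a black line and colours giving the camera call at the preset correlation. The maturing neutrophil list has the highest median, 1.66, and the erythroid list the lowest, -0.85; with an estimated correlation 0 of the 30 lists were called.

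Stem cell genes did not differ detectably, and B-cell lists were higher in the knockout, in part through single libraries. Cells carrying markers of mature blood lineages had been removed, so these lists do not measure B-cell differentiation in whole marrow. They cannot answer the title's question on its loss. The list of long-term haematopoietic stem cell markers had 11 of 28 members higher and 17 lower, with a median log2 fold change of -0.06 (camera adjusted p = 0.529), and 0 members passed either adjustment. Vwf stood at 92.5 ± 7.25 CPM in wild type and 68.1 ± 14.3 CPM in the knockout, and Hoxb4 at 5.25 ± 1.63 and 7.43 ± 1.32 CPM. Without wild type replicate 2 the stem cell list was called lower (adjusted p = 2.1e-05). Early lymphoid progenitor genes were not called (13 of 19 higher, median 0.13, camera adjusted p = 0.289), but were called higher without wild type replicate 1 (adjusted p = 0.0221). The pro-B and pre-B cell list rose, with 23 of 28 members higher, a median of 0.59 and a camera adjusted p of 0.00011 (adjusted p = 0.797 with an estimated correlation). Its median deviations were -0.05 and -0.26 in wild type replicates 1 and 2 and 0.06 and 0.37 in knockout replicates 1 and 2, and the call ended without knockout replicate 2 (adjusted p = 0.180). Vpreb3, a part of the pre-B cell receptor complex, stood at 0.780 ± 0.0313 CPM in wild type and 2.95 ± 0.594 in the knockout, Spib at 5.18 ± 0.895 and 11.9 ± 6.35 CPM, and Cd79b at 17.6 ± 4.74 and 26.4 ± 2.29 CPM, none passing either adjustment. Other members were high in knockout replicate 2 alone: Pax5 had 32 and 51 reads in wild type and 16 and 210 in the knockout, and Ebf1 31 and 29 against 22 and 78. Both knockout libraries lay above both wild type libraries for 10 of the 28 members. The mature B and plasma cell list rose with 21 of 21 members higher (median 0.69, camera adjusted p = 4.1e-05, adjusted p = 0.797 with an estimated correlation). Its median deviation was -0.98 in wild type replicate 2 against 0.18 in wild type replicate 1, 0.55 in knockout replicate 1 and 0.26 in knockout replicate 2. Fcrl1 stood at 0.976 ± 0.0697 and 2.22 ± 0.00165 CPM, and Cd22 at 5.65 ± 0.0491 and 9.10 ± 1.93 CPM, in wild type and knockout. The T-cell list rose with 15 of 15 members higher (median 0.63, camera adjusted p = 0.0013, adjusted p = 0.797 with an estimated correlation), and the call was lost without wild type replicate 2 (adjusted p = 0.461) or knockout replicate 1 (adjusted p = 0.0700). Natural killer and innate lymphoid cell genes were not called (11 of 16 higher, median 0.54, camera adjusted p = 0.188). They were called higher without wild type replicate 1 (adjusted p = 0.000134) or knockout replicate 2 (adjusted p = 0.00276) and lower without wild type replicate 2 (adjusted p = 0.0473).

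Erythroid and megakaryocytic genes and genes of cell division were lower in the knockout. The erythroid list fell, with 29 of 29 measured members lower, a median log2 fold change of -0.85 and a camera adjusted p of 8.6e-08 (adjusted p = 0.797 with an estimated correlation). The genotypes overlapped, because the median deviation was -0.11 and 1.01 in wild type replicates 1 and 2 and -1.15 and 0.28 in knockout replicates 1 and 2. Epb42, a protein of the red cell membrane, stood at 51.7 ± 24.1 CPM in wild type and 24.7 ± 13.8 CPM in the knockout, the globin gene Hbb-bs at 201 ± 98.4 and 98.2 ± 48.8 CPM, and Tfrc, the transferrin receptor, at 610.4 ± 169 and 400.4 ± 129 CPM. The megakaryocyte list fell with 15 of 18 members lower (median -0.35, camera adjusted p = 0.00305), the DNA replication list with 27 of 27 lower (median -0.22, camera adjusted p = 1.4e-05) and the mitosis list with 24 of 26 lower (median -0.16, camera adjusted p = 0.00621). With an estimated correlation the adjusted p was 0.797 for each of these 3 lists, and 0 members passed either adjustment. Pole, a replicative polymerase, stood at 178 ± 19.8 CPM in wild type and 139 ± 18.9 in the knockout, and the proliferation marker Mki67 at 1323 ± 368 and 1006 ± 244 CPM. Without wild type replicate 2 the adjusted p was 0.259 for DNA replication and 0.565 for mitosis, the latter then higher in the knockout. Without knockout replicate 1 it was 0.505 for mitosis and 0.735 for the megakaryocyte list, which was also lost without wild type replicate 1 (adjusted p = 0.140).

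**Figure D3:**
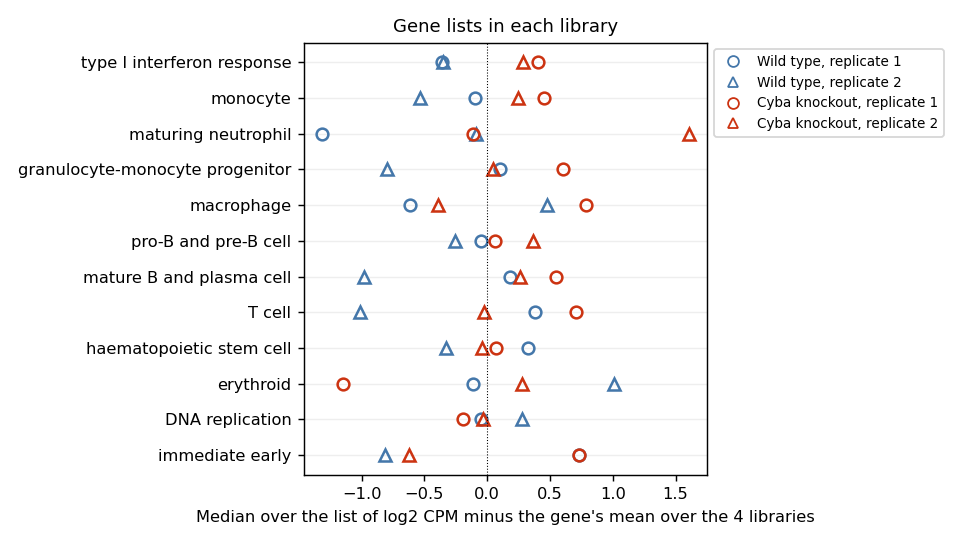
Median over each of 12 gene lists of log2 CPM minus the gene's mean over the 4 libraries, for wild type (blue) and Cyba knockout (red), replicate 1 as circles and replicate 2 as triangles. Both knockout libraries lie above both wild type libraries for the interferon list (0.40 and 0.29 against -0.36 and -0.35), while for the erythroid list knockout replicate 2 (0.28) lies above wild type replicate 1 (-0.11).

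Among lists for inflammation, metabolism and stress, the inflammatory response list rose with 21 of 24 members higher (median 0.41, camera adjusted p = 0.00757), and the list of mitochondrially encoded genes fell with 11 of 13 lower (median -0.15, camera adjusted p = 0.0113). With an estimated correlation the adjusted p was 0.797 for both. Bcl3 of the inflammatory list stood at 5.27 ± 2.79 CPM in wild type and 11.1 ± 1.09 in the knockout, and mt-Co2 at 3582 ± 370.3 and 2369 ± 649 CPM. The inflammatory call was lost without wild type replicate 2 (adjusted p = 0.461) or knockout replicate 1 (adjusted p = 0.355), and the mitochondrial call without wild type replicate 2 (adjusted p = 0.259) or knockout replicate 2 (adjusted p = 0.310). The list of nuclear genes of oxidative phosphorylation fell slightly, with 29 of 38 lower and a median of -0.07 (camera adjusted p = 0.0415, adjusted p = 0.817 with an estimated correlation), a call lost without wild type replicate 2 (adjusted p = 0.461, then higher), knockout replicate 1 (adjusted p = 0.241) or knockout replicate 2 (adjusted p = 0.107). The antioxidant list, which holds NRF2 targets and enzymes that remove reactive oxygen species, was not called, with 12 of 30 members higher and 18 lower (median -0.12, camera adjusted p = 0.801). Within it Glrx, glutaredoxin, stood at 52.4 ± 4.70 CPM in wild type and 73.8 ± 4.29 in the knockout, and Gsr, glutathione reductase, at 196 ± 55.0 and 311 ± 50.4 CPM. Glycolysis and hypoxia genes (median 0.29, camera adjusted p = 0.0585), the unfolded protein response (median 0.29, camera adjusted p = 0.263), p53 targets (median -0.09, mean 0.03, test direction lower, camera adjusted p = 0.532), immediate early genes (median -0.05, mean 0.16, test direction higher, camera adjusted p = 0.834) and stromal and endothelial genes (median -0.16, camera adjusted p = 0.529) were not called. Without wild type replicate 1 or without knockout replicate 2 calls appeared for glycolysis (adjusted p = 0.00556 and 0.0138, higher), the unfolded protein response (adjusted p = 0.0197 and 0.00046, higher) and immediate early genes (adjusted p = 0.0151 and 0.000555, higher). Immediate early genes were called lower without wild type replicate 2 (adjusted p = 0.000752) or knockout replicate 1 (adjusted p = 0.000871). Each comparison rested on 2 mice per genotype, with a common biological coefficient of variation of 0.2399. The direction of single-gene differences is given as measured, and none of them passed over all genes with the edgeR quasi-likelihood test.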

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

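The alternatives on the repair of the decimal points and on immunoglobulin genes were chosen after seeing the data; the others were set before the data were examined. The count of 0 genes called by edgeR held under both other scalings, both other filters, limma-voom, log2(TPM + 1), both other thresholds and all 4 added alternatives. DESeq2 called 31 genes (29 higher, 2 lower) and the likelihood ratio test 28 (25 higher, 3 lower), of which 23 were shared; log2(TPM + 0.1) called 1, Cyba, which was lower. The fits differ in how they estimate the spread, and the cause of the gap was not tested further. Without 1 library the count ranged from 0 to 2 (higher, 0 to 2); the 2 calls, Hspa1b and Igkv10-94, came without Cyba knockout replicate 2, and Hspa1b stood at 501 CPM in knockout replicate 1 and 32.1 in replicate 2. With the replicate block the count was 1165 (743 higher, 422 lower). The numbers come from the sample titles, which do not say that they mark a shared day or batch; deviations of same-numbered libraries correlated at 0.613 across genes. The log2 fold change of Cyba ranged from -5.43 to -4.64; its adjusted p, 0.305, passed the threshold with DESeq2 (-5.20), the likelihood ratio test (-5.19), log2(TPM + 0.1) (-5.08) and the replicate block (-5.17). The 17 gene lists called by camera went to 0 with an estimated correlation and to 0 with fry, and to between 12 and 24 in the other alternatives. Adjusted p with an estimated correlation and with fry were 0.797 and 0.859 for the pro-B and pre-B cell, maturing neutrophil and monocyte lists, 0.797 and 0.895 for granulocyte-monocyte progenitors, and 0.334 and 0.207 for the interferon list; with an estimated correlation camera has only the 2 residual degrees of freedom of 4 libraries, and the estimates ran from -0.059 for stromal genes to 0.985 for the erythroid list, with -0.023 for the interferon list. Without 1 library in turn, 6 lists were called in the same direction all 4 times: mature B and plasma cell, granulocyte-monocyte progenitor, maturing neutrophil, monocyte, erythroid and interferon. Adjusted p then ranged from 1.1e-12 to 0.180 for the pro-B and pre-B cell list, from 2.1e-05 to 0.700 for stem cells, from 5.4e-05 to 0.0425 for macrophages, from 2.2e-08 to 0.618 for eosinophils, from 0.00013 to 0.456 for natural killer cells, from 1.8e-05 to 0.565 for mitosis, from 0.000704 to 0.461 for oxidative phosphorylation and from 0.00056 to 0.0151 for immediate early genes, all but the first of these with a change of direction. Of the named genes, log2 fold changes crossed 0 for Vcam1 (-0.0321 to 1.398), Rag1 (-0.48 to 2.28), Btg2 (-0.0503 to 0.97), Slc40a1 (-0.79 to 0.29), Myc (-0.25 to 0.0374), Uty (-0.42 to 0.12) and Kdm5d (-0.10 to 0.26), and for Kdm5d also with log2(TPM + 1) (-0.0131) and log2(TPM + 0.1) (-0.037). Apart from those with TPM values, these turns arose where 1 genotype was left with 1 library, assumed to vary like the others. Immediate early genes were alike in same-numbered libraries, with median deviations of 0.73 and 0.73 in replicates 1 and -0.81 and -0.62 in replicates 2. Leaving out 1 library therefore set unequal replicate numbers against each other, which by itself turned their direction. Macrophage genes did not follow the numbers, at -0.62 and 0.79 in wild type and knockout replicates 1. The cause of the other turns was not tested. Log2 CPM correlated at 0.9868 between wild type 1 and knockout 1 and at 0.9814 between wild type 2 and knockout 2. Between the libraries of 1 genotype it correlated at 0.9747 in wild type and 0.979 in the knockout. Depth limits genes near the floor, such as Klk1 with 1 and 0 reads in wild type.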

Other observations

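Some genes differed strongly between libraries of the same genotype. Immunoglobulin transcripts were among the most abundant: Igha, the heavy chain constant region of IgA, stood at 5526 and 1438 CPM in wild type replicates 1 and 2 and at 15242 and 5096 CPM in knockout replicates 1 and 2, and Jchain at 1738 and 379 CPM and 3106 and 1025 CPM in the same order. Ighm stood at 7537, 931, 3522 and 2068 CPM. Immediate early genes had a median deviation of 0.73 in wild type replicate 1 and 0.73 in knockout replicate 1, against -0.81 and -0.62 in replicates 2. Fos stood at 1472 and 518 CPM in wild type and at 1492 and 450 CPM in the knockout, and Egr1 at 194 and 43.4 CPM and 204 and 21.9 CPM. The neutrophil alarmin S100a8 stood at 123 and 216 CPM in wild type and at 320 and 746 CPM in the knockout. Both knockout libraries thus lay above both wild type libraries. S100a9, also of the maturing neutrophil list, stood at 132 and 381 CPM and 347 and 1274 CPM in the same order, so its genotypes overlapped. These genes were chosen after their values were seen.

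All tests in this part were chosen after the result was seen: the interferon list was higher in both knockout libraries. If more mature neutrophils had brought these transcripts, the list would have had to follow the maturing neutrophil list between replicates 2 and 1 of a genotype. The median log2 difference needed was 0.796, and the interferon list's 95% bootstrap interval over genes was -0.318 to 0.263. This interval leaves out the spread between mice, so it argues against neutrophils as the whole source only if mice vary little. For monocytes the needed difference was -0.267, inside that interval, which also holds 0, so a larger monocyte share may contribute and cannot be told apart from a change within cells. Errors in the repaired counts are argued against by the 14 members with no damaged count, over which the list was still called higher (camera adjusted p = 4.3e-06 at the preset correlation). Plasmacytoid dendritic cells, whose list also rose and shares Irf7 and Bst2 with the interferon list, an effect of genotype and the mice's exposure to microbes were not tested as sources and stay open.

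Myeloid lists were higher and the erythroid list lower in the knockout, and both tests of this pattern were chosen after the result was seen. A lower share of erythroid cells would have raised the genes of all other cell types alike, and the maturing neutrophil list exceeded the stem cell list by 1.432 in median log2 difference (95% bootstrap interval over genes 1.17 to 1.63), which speaks against that share as the whole cause only if libraries vary little. By library this gap was -1.641 and 0.234 in wild type replicates 1 and 2 and -0.178 and 1.645 in knockout replicates 1 and 2, larger in the knockout within each replicate number but overlapping between genotypes, and the labels do not say that the numbers mark pairs, so this explanation stays open. Poorer removal of all lineage-positive cells from the knockout samples would have raised erythroid genes too if these came from lineage-positive cells. Their median deviation in knockout replicate 2, 0.279, lay between the 2 wild type libraries, while knockout replicate 1 lay below both. The list also holds genes of early erythroid cells, such as Gata1, Klf1 and Epor, and red cells had been lysed. Its direction therefore cannot decide on poorer removal. Poorer removal of all lineages, a different efficiency of the magnetic depletion for single lineages and a change in marrow composition with genotype cannot be told apart here.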
